A study of Lactuca sativa with 12 samples.

How the data were processed

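Poly(A)-selected RNA of whole lettuce leaves was sequenced on an Illumina platform after TruSeq library preparation, per the labels' protocols. Seedlings grew hydroponically and were untreated (CK) or received cadmium at 10 mg/L (Cd), selenium nanoparticles at 3 mg/L (SeNP) or both (CdSeNP), with 3 libraries per group and 12 in all. The series text calls the replicates biological. Groups and replicate numbers were taken from the labels, and each value column carries the name of 1 library.

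The deposited data are 6 tables, 1 per pair of groups. The authors' tools were fastp 0.23.0, Trimmomatic, HISAT2 2.2.1, StringTie 2.2.1 and DESeq2 1.34.0, per the submitters' processing notes, which give no role or order. The program that counted reads, whether it used strand, the genome build and the annotation are not given in the sources used here. The authors deposited whole-number read counts per gene and library without normalisation, per the file headers. They also deposited FPKM (fragments scaled by gene model length and library total) for the same libraries, per the file headers. The authors' log2 fold changes, p-values and adjusted p-values of the first-named group over the second stand in the same deposited tables. Each deposited table lists only genes at an adjusted p under 0.05 and an absolute log2 fold change over 1, so values of all other genes were not analysed here. The tables together hold 2264 genes, and 575 of them have values in all 12 libraries. Values of the same gene and library differed between tables at 0 genes. All 2102 RefSeq gene IDs matched the RefSeq annotation Lsat_Salinas_v11 with the same start and end, and 162 further IDs are loci added by the authors. Coordinates are whole-gene spans as the files give them, and exon positions were not used.

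Because only called genes are listed, no test across all genes was run, and the counts of genes called are the authors'. This fallback, the groups, the 32 gene lists, the rule for named genes and all alternatives but those named below were set before the data were examined. The number of genes tested was recovered from the ratio of adjusted to raw p. Total reads per library were recovered from counts, FPKM and gene spans, over genes with at least 200 counts whose totals lay within 0.2% of the commonest one. The totals were 27.2, 27.1 and 26.7 M reads in CK 1 to CK 3, 30.4, 31.4 and 28.9 M in Cd, 25.6, 28.7 and 23.3 M in SeNP, and 24.9, 23.8 and 28.6 M in CdSeNP. Gene levels are given as the mean ± SD of FPKM over 3 libraries. Standard errors of the authors' log2 fold changes were recovered as the change divided by the normal quantile of their p. For a group with no counts, the fold was computed against a floor of 3 counts summed over its 3 libraries and is a lower bound. Such bounds cover counting error only. Reads shared between near-identical copies or overlapping genes make the values of single members of gene families uncertain.

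Each gene list was a set of words matched on the RefSeq, Swiss-Prot and NR descriptions and the names of KEGG orthologs and Pfam domains. Its higher and lower calls were compared with all other calls of the same table by a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over 192 tests. The test asks whether a list leans more to 1 side than the rest of the table, so a list whose members all rose can miss it where most of the table rose. Genes of a list share regulation and are not independent, which makes these p-values too small. The difference between the Cd response with and without nanoparticles was tested as an interaction with edgeR's quasi-likelihood test on the 575 genes, with size factors recovered from the counts and the authors' fold changes. The overlaps reported between comparisons that share libraries were set beside n1 × n2 / N and 5 simulations of unchanged groups. In these simulations no gene changed and genes varied independently, so the simulated lists held only false calls. Their overlaps therefore do not show how much shared libraries add to overlaps of the real lists. With 3 libraries against 3, an exact permutation test of 1 gene cannot go below 0.1, and none was run.

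Named genes were, for Cd, SeNP and CdSeNP against CK and CdSeNP against Cd, the 6 largest increases and 6 largest decreases with a functional description, a mean of at least 5 FPKM in the higher group and no overlap between libraries. To these came up to 2 genes with the smallest adjusted p in each list described, and the 5 genes with the largest change in Cd called the opposite way in CdSeNP against Cd. The lists described and 23 further genes were chosen after their values were seen. These are 8 added loci on chromosome 5 and 15 genes, most of them of metal balance, superoxide removal, photosynthesis or chlorophyll synthesis.

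Alternatives were edgeR and DESeq2 refits of the listed genes, the replicate number as a block, an adjusted p limit of 0.01, an absolute log2 fold change of at least 2, no fold threshold, NR or Swiss-Prot descriptions alone, and leaving out each library in turn. A call was kept where the refit's p did not exceed the authors' largest listed p of that table and the absolute log2 fold change was at least 1, so genes that would newly enter are not seen. Counts with a library left out or with the block are edgeR refits, to be read against the edgeR refit with all libraries. A comparison that does not use the library left out kept the authors' calls. Scaling to library totals, with the authors' p or in an edgeR refit, and the weight given to CK 2 were chosen after seeing the data. On simulated counts with known changes, the refits recovered 99 to 100% of genes changed 4-fold and 92 to 100% of genes changed 3-fold in the 6 comparisons, with 0 to 7 unchanged genes called. The interaction recovered 97% and 86%, with 7 of 375 unchanged genes called. Random lists fell under 0.05 by Fisher's exact test in 3.0 to 4.3% of 1000 draws. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, DESeq2 1.42.0 and limma 3.58.1 were used.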

Results

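Leaf RNA of hydroponically grown red oak-leaf lettuce (Lactuca sativa) was sequenced from 4 groups of 3 libraries. CK was untreated. Cd received cadmium at 10 mg/L, SeNP received biosynthesised selenium nanoparticles at 3 mg/L, and CdSeNP received both. The labels give the cadmium dose once as cadmium and once as a hydrated cadmium chloride, so the amount of metal ion is uncertain. The series text calls the replicates biological, and all 12 libraries carry the same batch label. Sequencing depth recovered from the files ran from 23.3 M reads in SeNP 3 to 31.4 M reads in Cd 2. The values come from 6 tables of pairwise comparisons, each of which lists the genes called by the authors and no others, so a gene missing from a table was not called there.

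Replicate libraries differed by more than counting noise in every group. Over the listed genes, the chi-square per degree of freedom between replicates lay between 5.03 and 14.14 in Cd, SeNP and CdSeNP. CK 1 and CK 3 differed by 8.68, whereas CK 2 differed from CK 1 by 46.1 and from CK 3 by 41.7. CK 2 therefore stood apart from the other 2 controls. For a set of genes, its place was measured on the log2 scale, with 0 at the mean of CK 1 and CK 3 and 1 at the treated mean. This place is given below for gene groups of the comparisons with CK.

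**Figure D1:**
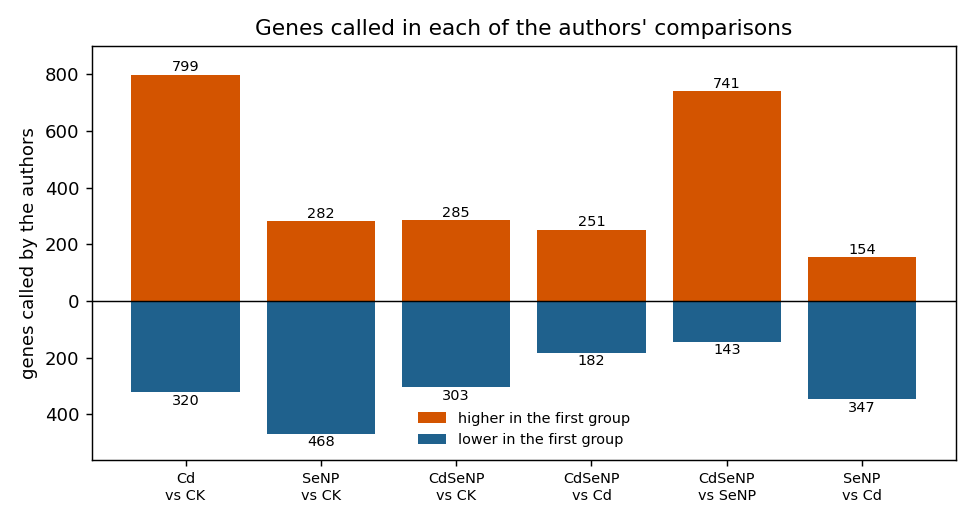
Number of genes that the authors called in each of their 6 comparisons (vertical axis), with genes higher in the first-named group above 0 and genes lower below 0. Cd against CK had 799 genes higher and 320 lower, and CdSeNP against SeNP had 741 higher and 143 lower.

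The comparison of Cd with CK asks how leaves responded to cadmium. Genes of iron acquisition were among those that rose most. The transcription factor ORG2 (LOC111878349, chromosome 5, 325658829 to 325661149, minus strand), a bHLH regulator induced by iron deficiency in Arabidopsis, had no counts in CK and 13.2 ± 0.616 FPKM in Cd (SD, n = 3). A second ORG2 gene (LOC111878326, 325822992 to 325825348) went from 0 to 10.6 ± 0.407 FPKM, and bHLH100 (LOC111878325, 325991553 to 325993914) from 0.095 ± 0.096 to 8.45 ± 0.663 FPKM (SD, n = 3 each). Another ORG2 gene (LOC111878327) lies on the same chromosome and rose from 0.081 ± 0.053 to 1.58 ± 0.238 FPKM. Reads could be shared among these neighbouring copies. Against a floor of 3 counts summed over the control group, LOC111878349 was at least 641.1-fold and LOC111878326 at least 328.7-fold higher in Cd. Ferric reduction oxidase 2 (LOC111894637), which reduces iron at the cell surface, rose from 0.2 ± 0.026 to 0.999 ± 0.148 FPKM. All 8 called members of the iron-deficiency list were higher, including scopoletin 8-hydroxylase and 2 homologs of 1-aminocyclopropane-1-carboxylate oxidase. Against the share of higher genes in the whole table, the list as such did not pass Fisher's exact test (adjusted p = 0.56), although each member passed its own test in the authors' deposited table. The place of CK 2 over these 8 genes was -0.013 (quartiles -0.04 and 0.009).

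Transporters of metal ions changed with them. Oligopeptide transporter 3 (LOC111920790, chromosome 7, 16632456 to 16635576), which moves iron in the phloem, rose from 7.45 ± 0.968 FPKM in CK to 54.8 ± 1.15 in Cd (SD, n = 3). The authors' deposited table gives it a log2 fold change of 2.76 (standard error 0.12 recovered from its p) and an adjusted p of 2.2e-123 with DESeq2. Nramp3, which exports metals from the vacuole, rose at 2 genes of this name, from 19.8 ± 1.57 to 69.5 ± 2.57 FPKM at LOC111896352 and from 6.07 ± 0.294 to 22.0 ± 0.947 FPKM at LOC111902752. Of 16 called metal transport genes 11 were higher and 5 lower (adjusted p = 1, Fisher's exact test). A pair of genes for vacuolar iron transporter homolog 4 on chromosome 5 went opposite ways: LOC111899495 rose from 2.33 ± 0.845 to 12.3 ± 4.14 FPKM, and LOC111899502 fell from 2.45 ± 0.787 to 0.166 ± 0.082 FPKM. Among 8 called genes of metal chelation, 4 rose and 4 fell (adjusted p = 0.72, Fisher's exact test). Metallothionein-like protein 1 (LOC111896763) rose from 356 ± 51.3 to 887 ± 62.6 FPKM. The iron-storage protein ferritin fell at 3 genes. LOC111919692 fell from 48.5 ± 9.93 to 5.85 ± 0.549 FPKM, LOC111908574 from 148 ± 12.9 to 25.6 ± 1.58 FPKM, and LOC111879873 from 96.7 ± 3.50 to 52.0 ± 0.718 FPKM. The call of LOC111879873 ended without CK 1 and with library totals as scaling. The iron-sulfur protein NEET (LOC111903255) fell from 9.20 ± 0.851 to 1.77 ± 0.125 FPKM, and plastidial pyruvate kinase 4 (LOC111888822) from 7.76 ± 0.411 to 1.36 ± 0.107 FPKM.

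Photosynthesis genes fell. Of the 32 called genes that matched this list, 30 were lower in Cd and 2 higher (adjusted p = 1.9e-13, Fisher's exact test), and 24 of the 30 stayed past the fold threshold when library totals replaced the authors' scaling. The 30 were mostly chlorophyll a-b binding proteins of the light-harvesting antennae, subunits of photosystem I and small subunits of Rubisco. A light-harvesting protein of photosystem II (LHCII type 1, LOC111895045, chromosome 1, 134932729 to 134933678) fell from 327 ± 44.8 FPKM to 41.5 ± 3.25 (SD, n = 3). Its log2 fold change was -3.10, with an adjusted p of 3e-120, in the authors' deposited table (DESeq2). Chlorophyll a-b binding protein 5 (LOC111895560) fell from 571 ± 41.9 to 172 ± 9.57 FPKM, and photosystem I subunit III (LOC111898563) from 3313 ± 92.0 to 1525 ± 27.5 FPKM. The 2 genes that rose, basic blue protein and blue copper protein, are small copper proteins outside the photosynthetic apparatus, and a rop guanine nucleotide exchange factor among the 30 matched the list's words without belonging to it. The place of CK 2 over the 30 lower genes was 0.108 (quartiles 0.039 and 0.135). At an absolute log2 fold change of at least 2, 2 genes were lower and the list's call ended (adjusted p = 0.52, Fisher's exact test).

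Genes of DNA replication and mitosis rose together. On the cell division list, 116 genes were higher in Cd and 1 was lower (adjusted p = 2.6e-15, Fisher's exact test), among them core histones, the MCM helicase subunits, mitotic cyclins and kinesins. Proliferating cell nuclear antigen, the sliding clamp of DNA polymerase, rose from 6.19 ± 0.698 to 15.7 ± 2.21 FPKM at LOC111880340 and from 1.30 ± 0.931 to 9.35 ± 1.25 FPKM at LOC111919730 (SD, n = 3). CK 2 lay nearer the treated level than the other controls did: its median place over the 116 genes was 0.68 (quartiles 0.618 and 0.715), against -0.488 for CK 1 and -0.52 for CK 3, each placed by the other controls. With edgeR 90 of them were called with all libraries and all 116 without CK 2. Leaving out the control nearest the treated level widens the difference, so the latter count is no independent support. The count was 36 without CK 1, 23 without CK 3, 37 without Cd 1, 18 without Cd 2 and 40 without Cd 3. In these settings Fisher's exact test gave the list an adjusted p of at most 0.048, without Cd 2. The count was 114 with DESeq2 and 116 with library totals and the authors' p, or with the replicate number as a block. It was 69 at an adjusted p under 0.01 and 72 with NR descriptions alone, and at an absolute log2 fold change of at least 2 it was 9 and the list's call ended (adjusted p = 1, Fisher's exact test).

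Other genes showed large changes in Cd. EPIDERMAL PATTERNING FACTOR-like protein 1 (LOC111910137, chromosome 5, 291153223 to 291155217), of a family of secreted peptides, had no counts in CK and 18.7 ± 0.953 FPKM in Cd (SD, n = 3), which was at least 924.9-fold higher. A locus added to the RefSeq genes (chromosome 8, 86132759 to 86159323), described as phosphopantothenoylcysteine decarboxylase subunit VHS3, rose from 0.036 ± 0.031 to 5.11 ± 0.295 FPKM. A vicilin-like seed storage protein (LOC111919377) rose from 0.356 ± 0.11 to 36.9 ± 2.46 FPKM. ECERIFERUM 26 (LOC111905151), of cuticular wax synthesis, fell from 84.3 ± 16.1 to 23.6 ± 0.985 FPKM, and 3-ketoacyl-CoA synthase 20 (LOC111915106) from 12.4 ± 0.321 to 6.10 ± 0.323 FPKM. On the list of epidermis and cuticle markers 20 genes rose and 7 fell (adjusted p = 1, Fisher's exact test), and the place of CK 2 over the 20 was 0.421 (quartiles 0.165 and 0.525). Ribosomal protein S19-3 (LOC111884917) had 47.6 ± 35.0 FPKM in CK and 4.87 ± 0.845 in Cd, with a wide spread among the controls.

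Genes of 3 further lists were lower more often than the rest of the table. On the list of sesquiterpene lactone and terpene synthase words, 11 fell and 4 rose (adjusted p = 0.0083, Fisher's exact test). Most of these are cytochromes P450 and terpene synthases that matched by their KEGG ortholog or Pfam domain, so the list rests on those annotations. They include cytochrome P450 736A117 (LOC111897186, 4.45 ± 0.403 to 2.25 ± 0.091 FPKM), desmethyl-deoxy-podophyllotoxin synthase (LOC111896888, 29.5 ± 6.96 to 13.1 ± 0.924 FPKM), by its name an enzyme of lignan synthesis, and germacrene A synthase (LOC111909135, 84.0 ± 17.9 to 45.7 ± 2.51 FPKM). On the ethylene list 11 fell and 6 rose (adjusted p = 0.033, Fisher's exact test), with 1-aminocyclopropane-1-carboxylate synthase 3 (LOC111900308), an enzyme of ethylene synthesis, down from 6.33 ± 1.25 to 1.69 ± 0.055 FPKM. A homolog of the next enzyme, 1-aminocyclopropane-1-carboxylate oxidase homolog 1 (LOC111897251), fell from 15.3 ± 2.38 to 7.69 ± 0.561 FPKM. On the abscisic acid list 7 fell and 2 rose (adjusted p = 0.042, Fisher's exact test). The place of CK 2 over the lower genes was 0.284 for the first list (quartiles -0.019 and 0.458), 0.42 for ethylene (quartiles 0.295 and 0.581) and 0.309 for abscisic acid (quartiles 0.231 and 0.431). These 3 calls ended in several settings. Without CK 1, CK 3, Cd 1, Cd 2 or Cd 3 in that order, the adjusted p of Fisher's exact test was 0.1, 0.33, 0.31, 0.31 and 0.53 for the first list, 0.58, 0.33, 0.59, 0.44 and 0.63 for ethylene, and 1, 0.33, 0.59, 0.99 and 0.99 for abscisic acid. The genes lower numbered 8, 7, 8, 7 and 6 for the first list and 8, 7, 6, 6 and 5 for the second. For abscisic acid 1, 5, 4, 2 and 2 were lower, and without CK 1 the list's lean turned. With library totals the adjusted p of Fisher's exact test was 0.056, 0.058 and 0.52, with 7, 8 and 3 genes lower. With Swiss-Prot descriptions alone it was 0.58, 0.23 and 0.27, with 2, 9 and 4 genes lower. With NR descriptions alone it was 0.89 for the first list, with 1 gene lower, and 0.21 for ethylene, with 9. The ethylene call also ended with edgeR (Fisher's exact test, adjusted p = 0.11), with the replicate number as a block (0.057) and at an absolute log2 fold change of at least 2 (1), and the abscisic acid call with edgeR (0.078), DESeq2 (0.052) and an adjusted p limit of 0.01 (0.17). Calls of single genes ended as well, for LOC111897186 without Cd 3, for LOC111897251 without Cd 1 or Cd 2, for LOC111909135 without Cd 1, CK 1 or CK 3, and for all 3 with library totals.

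In all, the authors' deposited table listed 799 genes higher and 320 lower in Cd at an adjusted p under 0.05 and at least a 2-fold change (log2 of 1), out of 23049 genes tested. Scaling to library totals moved every log2 value by 0.119 and left 799 higher and 225 lower. The share higher went from 71.4% to 78.0%. With only called genes listed, this shift could remove lower calls alone, so the share could only rise. An edgeR refit of the listed genes with library totals left 714 higher and 211 lower. Genes higher numbered 345 without Cd 2, 417 without Cd 3, 457 without Cd 1, 378 without CK 3 and 432 without CK 1, and genes lower 207 without Cd 2 and 205 without Cd 3, at the same p limit with fewer libraries. These are edgeR refits, and the edgeR refit with all libraries left 669 higher and 303 lower. Without CK 2 there were more, 777 higher and 311 lower. Over all 1119 listed genes the place of CK 2 was 0.435 (quartiles 0.178 and 0.631).

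SeNP was compared with CK to see what the nanoparticles did without cadmium. The superoxide dismutases, which remove superoxide, changed in opposite directions. The chloroplast iron enzyme (LOC111905867, chromosome 8, 15473345 to 15483628) fell from 139 ± 0.09 FPKM to 19.99 ± 2.98 (SD, n = 3), and stood at 132 ± 8.36 in Cd and 129 ± 4.79 in CdSeNP. The authors' deposited table gives a log2 fold change of -2.83 (standard error 0.12 recovered from its p) and an adjusted p of 9.3e-128 with DESeq2. The copper-zinc enzymes rose from 79.1 ± 8.25 to 231 ± 23.6 FPKM at LOC111882980 and from 231 ± 72.5 to 491 ± 24.5 FPKM at LOC111897744. Their copper chaperone (LOC111898919) rose from 26.3 ± 3.29 to 56.0 ± 2.72 FPKM. The alternative oxidase ubiquinol oxidase 2 (LOC111897513) fell from 20.9 ± 2.34 to 5.09 ± 0.184 FPKM. The antioxidant list held these 5 genes, 3 higher and 2 lower (adjusted p = 0.85, Fisher's exact test). The call of LOC111897744 ended without CK 1 or CK 3.

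Of 7 called metal transport genes 6 were lower in SeNP (adjusted p = 0.74, Fisher's exact test). Zinc transporter 1 (LOC111880346, chromosome 8, 112612028 to 112613913) fell from 18.3 ± 0.936 to 1.84 ± 0.369 FPKM (SD, n = 3), copper transporter 5 (LOC111893192) from 149 ± 10.3 to 47.1 ± 7.68 FPKM, and the metal-nicotianamine transporter YSL3 (LOC111920401) from 80.7 ± 10.7 to 26.2 ± 2.92 FPKM. Basic blue protein (LOC111904155) rose from 14.3 ± 7.38 to 73.7 ± 9.59 FPKM and laccase-11 (LOC111916163), an oxidase of lignin formation, from 2.45 ± 0.291 to 5.99 ± 0.318 FPKM. The cupredoxin LOC111881903, a copper protein like basic blue protein, fell from 8.80 ± 3.33 to 3.83 ± 0.753 FPKM, and the cupredoxin LOC111881904 from 6.82 ± 2.17 to 3.35 ± 0.537 FPKM. Both calls ended without CK 3 or any one SeNP library, and that of LOC111881904 also without CK 1. Dirigent protein 22 (LOC111898986) fell from 13.9 ± 2.16 to 4.37 ± 0.492 FPKM and an isoflavone reductase homolog (LOC111898507) from 23.6 ± 2.56 to 4.70 ± 0.898 FPKM. Over the 12 antioxidant and metal transport genes the place of CK 2 was 0.158 (quartiles 0.077 and 0.27), with values of 0.018 for the iron superoxide dismutase, 0.053 for zinc transporter 1 and 0.514 for LOC111897744.

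Genes of the ethylene list fell. On this list 22 genes were lower and 2 higher in SeNP (adjusted p = 0.033, Fisher's exact test), the lower ones mostly ethylene-responsive transcription factors. ERF027 (LOC111903232) fell from 15.8 ± 1.96 to 5.45 ± 1.23 FPKM and 1-aminocyclopropane-1-carboxylate oxidase 3 (LOC111904962) from 171 ± 20.9 to 84.3 ± 7.98 FPKM (SD, n = 3). On the jasmonate list 16 were lower and 1 higher (adjusted p = 0.059, Fisher's exact test). Jasmonate-induced oxygenase 2 (LOC111901270) fell from 10.8 ± 2.25 to 2.92 ± 0.301 FPKM, the jasmonate-conjugating enzyme JAR6 (LOC111876787) from 23.2 ± 3.96 to 9.09 ± 0.306 FPKM, and the jasmonate repressor TIFY 10A (LOC111910354) from 11.9 ± 3.90 to 2.91 ± 0.388 FPKM. The F-box protein PP2-B15 (LOC111905931) fell from 5.66 ± 1.62 to 1.42 ± 0.446 FPKM. Among 10 called heat shock and chaperone genes 9 were lower (adjusted p = 0.55, Fisher's exact test), including heat shock cognate 70 kDa protein 2 at LOC111912265 (17.5 ± 1.35 to 8.79 ± 0.679 FPKM) and LOC111885224 (2.10 ± 0.446 to 0.821 ± 0.017 FPKM). CK 2 lay part of the way to SeNP, with a place of 0.443 over the 22 ethylene genes (quartiles 0.276 and 0.562) and 0.356 over the 16 jasmonate genes (quartiles 0.316 and 0.441). Over the 9 heat shock and chaperone genes its place was 0.226 (quartiles 0.055 and 0.271). The adjusted p of Fisher's exact test for ethylene was 0.069 with edgeR, 0.057 with DESeq2, 0.071 with an adjusted p limit of 0.01, 0.082 and 0.056 with NR or Swiss-Prot descriptions alone, and 1 at an absolute log2 fold change of at least 2 (3 genes lower). It was 0.21 without CK 1 (17 genes lower), 0.33 without CK 3 (16), 0.37 without SeNP 1 (14), 0.69 without SeNP 2 (10) and 0.68 without SeNP 3 (13). Calls of LOC111904962 and LOC111912265 ended without SeNP 2, CK 1 or CK 3, and that of LOC111912265 also with library totals.

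Cell division genes rose in SeNP as well, 78 higher and 0 lower (adjusted p = 6.8e-35, Fisher's exact test). Histone H4 (LOC111909605) went from 17.5 ± 7.92 to 49.3 ± 0.892 FPKM and histone H2B.1 (LOC111909452) from 17.6 ± 4.92 to 37.1 ± 1.33 FPKM (SD, n = 3). Reads of histone genes can be shared among near-identical copies. The place of CK 2 over the 78 genes was 0.703 (quartiles 0.649 and 0.724). With edgeR 62 of them were called with all libraries and all 78 without CK 2, the control nearest SeNP, so the latter count is no independent support. The count was 32 without CK 1, 24 without CK 3, 12 without SeNP 1, 13 without SeNP 2 and 13 without SeNP 3. It was 41 at an adjusted p under 0.01 and 48 with NR descriptions alone. In these settings Fisher's exact test gave the list an adjusted p of at most 3.5e-07, without SeNP 1. The call of LOC111909452 ended without CK 1, CK 3 or any SeNP library. Epidermis and cuticle markers were higher at 6 genes and lower at 0 (adjusted p = 0.04, Fisher's exact test). The GDSL esterase/lipase LOC111886847 rose from 2.50 ± 1.52 to 10.5 ± 1.60 FPKM and its neighbour LOC111886836 from 0.95 ± 0.486 to 2.54 ± 0.224 FPKM. Non-specific lipid-transfer protein 1 (LOC111887989) rose from 10.97 ± 9.25 to 43.2 ± 11.1 FPKM and glycine-rich protein 5-like (LOC111907682) from 9.27 ± 8.42 to 46.2 ± 5.33 FPKM. Over the 6 markers CK 2 had a place of 0.62 (quartiles 0.53 and 0.657). For the markers the adjusted p of Fisher's exact test was 0.057 with edgeR, 0.2 with DESeq2, 0.056 with library totals, 0.054 with the replicate number as a block, 0.26 with an adjusted p limit of 0.01 (3 genes higher) and 1 at an absolute log2 fold change of at least 2 (1 gene higher). It was 0.061 without CK 1 (4 genes higher), 0.051 without CK 3 (4), 0.82 without SeNP 2 (1) and 0.74 without SeNP 3 (1). The call of LOC111886836 ended without SeNP 2, SeNP 3 or CK 3, and that of LOC111887989 without SeNP 2 or SeNP 3. Dehydrin Rab18 (LOC111913327) was among the largest increases, from 1.00 ± 0.378 FPKM in CK to 5.43 ± 1.21 in SeNP. A chloroplast ribosomal protein L2-like gene (LOC128126385) was at 0.31 ± 0.138 FPKM in CK, 12.9 ± 5.30 in SeNP and 10.1 ± 8.15 in CdSeNP, and its call in CdSeNP ended without CK 1, CK 3 or CdSeNP 3.

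In all, 282 genes were higher and 468 lower in SeNP than in CK in the authors' deposited table, of 22656 tested. An edgeR refit of the listed genes left 205 higher and 448 lower with all libraries, and 281 and 463 without CK 2. Genes higher numbered 107 without CK 1, 86 without CK 3, 76 without SeNP 1, 64 without SeNP 2 and 63 without SeNP 3, and genes lower 298 without CK 3, 259 without SeNP 1, 213 without SeNP 2 and 272 without SeNP 3. At an adjusted p under 0.01, 167 genes were higher, and an edgeR refit of the listed genes with library totals left 176 higher and 405 lower. CK 2 had a place of 0.492 over all 750 genes (quartiles 0.24 and 0.673) and lay over 0.3 at 516 of them (68.8%).

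The comparison of CdSeNP with CK gives the response to both treatments together. Genes of iron acquisition were again higher and photosynthesis genes lower. On the iron-deficiency list 5 genes rose and 0 fell (adjusted p = 0.23, Fisher's exact test), namely 3 ORG2 genes, bHLH100 and ferric reduction oxidase 2. The ORG2 gene LOC111878349 reached 12.4 ± 0.454 FPKM, LOC111878326 reached 8.78 ± 0.858, bHLH100 reached 9.14 ± 0.45, and EPIDERMAL PATTERNING FACTOR-like protein 1 reached 16.1 ± 0.365 FPKM (SD, n = 3). Oligopeptide transporter 3 stood at 54.5 ± 3.19 FPKM and Nramp3 (LOC111896352) at 72.5 ± 2.14. Ferritin LOC111919692 stood at 4.84 ± 0.218 FPKM and LOC111908574 at 34.2 ± 3.87. On the photosynthesis list 28 genes were lower and 1 higher (adjusted p = 2.6e-06, Fisher's exact test), with LHCII type 1 at 38.9 ± 0.439 FPKM. Chlorophyll a-b binding protein 13 (LOC111904852) fell from 1136 ± 34.8 to 361 ± 5.66 FPKM, and the place of CK 2 over the 28 genes was 0.099 (quartiles 0.035 and 0.124). The list's call ended at an absolute log2 fold change of at least 2, with 7 genes lower (adjusted p = 0.077, Fisher's exact test). NEET stood at 1.59 ± 0.109 FPKM, plastidial pyruvate kinase 4 at 1.66 ± 0.187, the isoflavone reductase homolog at 4.36 ± 0.745, and a vicilin (LOC111921670) fell from 156 ± 28.9 to 34.3 ± 2.87 FPKM. Dehydrin Rab18 (LOC111913327, chromosome 2, 166825393 to 166826214), a protein that accumulates under water deficit, rose from 1.00 ± 0.378 FPKM in CK to 59.4 ± 9.69. The vicilin-like gene LOC111919377 stood at 17.0 ± 1.11 FPKM. Of the genes called in Cd and in CdSeNP against CK, 341 had the same direction and 0 the opposite. Independent lists would share 14.2 in the same direction, and simulated unchanged groups with the same controls shared 7 to 9 false calls. Part of the excess may come from the shared controls, and the simulations do not show how much. The 341 became 275 in edgeR refits with all libraries. It became 215 without CK 1, 197 without CK 3, 225 without CdSeNP 1, 213 without CdSeNP 2 and 218 without CdSeNP 3.

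Cell division genes were higher at 20 genes and lower at 1 (adjusted p = 0.00013, Fisher's exact test), with LOC111919730 at 4.47 ± 1.04 FPKM and histone H4 (LOC111909605) at 38.3 ± 2.56 FPKM. The place of CK 2 over the 20 genes was 0.728 (quartiles 0.668 and 0.796). The count was 20 without CK 2, 4 with edgeR (Fisher's exact test, adjusted p = 0.7), 9 with the replicate number as a block (0.083), 11 at an adjusted p under 0.01, 13 with NR descriptions alone, and 0 without CK 1, CK 3 or any one CdSeNP library, and these 2 genes' own calls ended without the same libraries. In all, the authors' deposited table listed 285 genes higher and 303 lower, of 22856 tested. Scaling to library totals moved every log2 value by 0.088 and left 285 higher and 245 lower. The share higher went from 48.5% to 53.8%. With only called genes listed, this shift could remove lower calls alone, and genes newly higher cannot be seen. The direction of this change was therefore fixed beforehand. An edgeR refit of the listed genes with library totals left 227 higher and 221 lower. At the authors' scaling the edgeR refit left 206 and 285 with all libraries, and 233 and 288 without CK 2. Genes higher numbered 166 without CK 1, 149 without CK 3, 133 without CdSeNP 1, 133 without CdSeNP 2 and 136 without CdSeNP 3. The place of CK 2 over all 588 genes was 0.134 (quartiles -0.137 and 0.4).

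**Figure D2:**
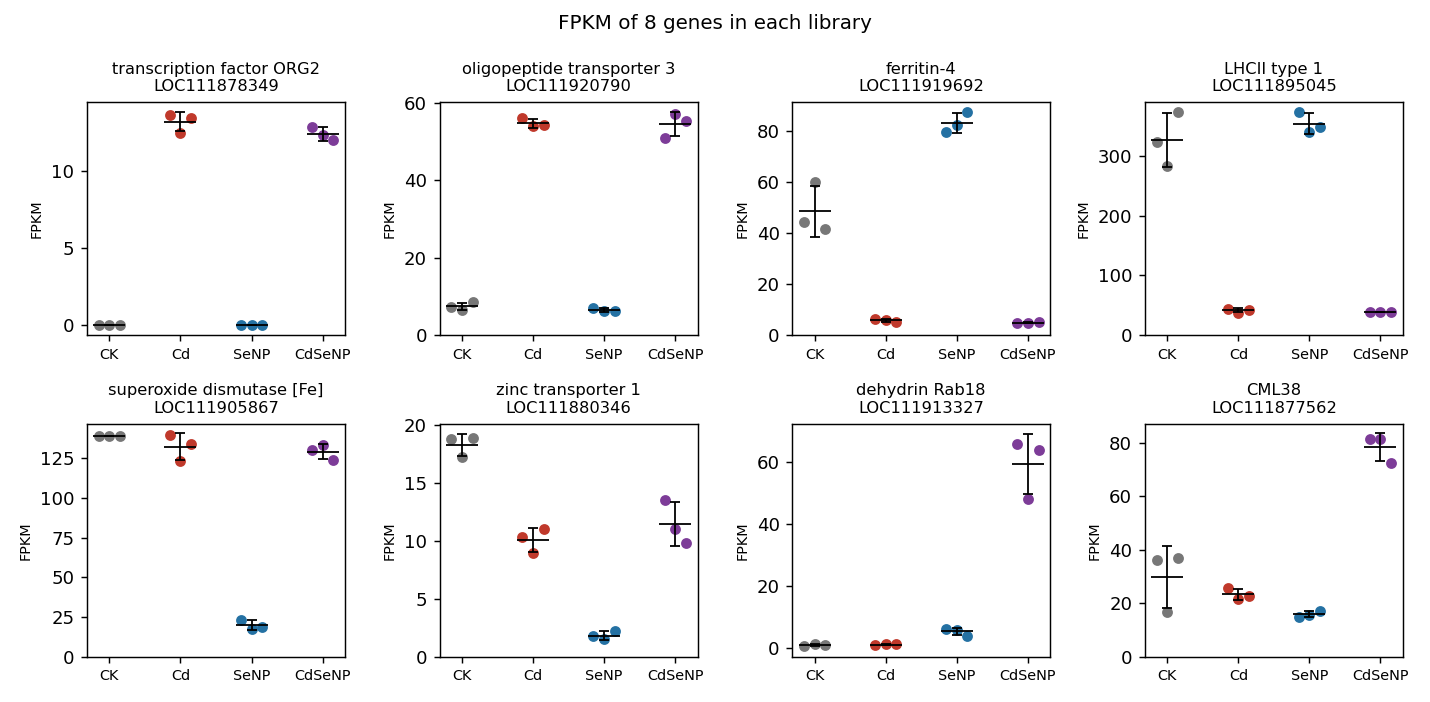
FPKM (vertical axis, linear) of 8 genes in CK, Cd, SeNP and CdSeNP; points are libraries, the horizontal dash is the mean and the bar the SD (n = 3). ORG2 and oligopeptide transporter 3 were higher, and ferritin-4 and LHCII type 1 lower, in Cd and CdSeNP, the iron superoxide dismutase and zinc transporter 1 were lowest in SeNP, and dehydrin Rab18 and CML38 were highest in CdSeNP.

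CdSeNP was compared with Cd to see what the nanoparticles changed in cadmium-treated plants. Dehydrin Rab18 differed most among the named genes, at 1.10 ± 0.148 FPKM in Cd and 59.4 ± 9.69 in CdSeNP, and it stood at 1.00 ± 0.378 in CK and 5.43 ± 1.21 in SeNP (SD, n = 3). Its log2 fold change was 5.80 (standard error 0.20 recovered from its p) with an adjusted p of 5.7e-188 in the authors' deposited table (DESeq2). A cluster of 3 genes for xyloglucan endotransglucosylase/hydrolase protein 23, a cell wall enzyme, rose on chromosome 8: LOC111909625 from 15.1 ± 1.41 to 58.6 ± 4.71 FPKM, LOC111909622 from 17.8 ± 1.30 to 63.5 ± 7.77, and LOC111909624 from 32.3 ± 3.39 to 115 ± 9.35. Reads may be shared among these copies. The calcium-binding protein CML38 (LOC111877562) rose from 23.3 ± 2.06 to 78.5 ± 5.24 FPKM and syntaxin-121 (LOC111898570), of vesicle fusion at the plasma membrane, from 4.32 ± 0.703 to 15.6 ± 1.08. In CK these 5 genes stood at 16.4 ± 7.12, 22.3 ± 8.996, 41.2 ± 16.2, 29.95 ± 11.6 and 8.17 ± 3.69 FPKM in the order named, and CK 2 was the lowest of the 3 controls at each. Syntaxin-121 was at 2.88 ± 0.618 FPKM in SeNP.

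All 4 called WRKY transcription factors were higher in CdSeNP than in Cd (adjusted p = 0.6, Fisher's exact test), with WRKY 31 (LOC111891013) from 4.92 ± 0.044 to 14.8 ± 1.59 FPKM (6.78 ± 3.01 in CK and 2.37 ± 0.531 in SeNP) and WRKY 53 (LOC111890844) from 45.1 ± 1.37 to 92.5 ± 8.52 (SD, n = 3). On the abscisic acid list 14 genes were higher and 2 lower (adjusted p = 0.18, Fisher's exact test), among them CYP707A2 (LOC111898519), which breaks abscisic acid down, from 62.4 ± 3.84 to 162 ± 11.9 FPKM. Pathogen defence genes went both ways, 13 higher and 13 lower (adjusted p = 0.85, Fisher's exact test). Endochitinase EP3 (LOC111901424) rose from 19.0 ± 1.59 to 41.6 ± 2.29 FPKM and leucine-rich repeat extensin-like protein 5 (LOC111884960) from 3.76 ± 0.308 to 11.9 ± 0.446. The 6 called genes that matched the photosynthesis list were higher (adjusted p = 0.32, Fisher's exact test), and they are cupredoxins, copper proteins outside photosynthesis, such as LOC111881903 (5.63 ± 0.633 to 15.2 ± 1.32 FPKM) and LOC111881904 (4.31 ± 0.324 to 10.5 ± 1.06 FPKM).

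Epidermis and cuticle markers, a list that includes lipid-transfer proteins, were lower in CdSeNP than in Cd at 9 genes and higher at 0 (adjusted p = 0.0083, Fisher's exact test). The GDSL esterase/lipases LOC111886847 and LOC111886836 fell from 20.9 ± 7.20 to 6.86 ± 0.523 FPKM and from 5.07 ± 1.52 to 1.53 ± 0.209 (SD, n = 3). Lipid-transfer proteins fell from 19.4 ± 5.18 to 4.77 ± 3.45 FPKM at LOC111915888 and from 35.6 ± 15.7 to 9.19 ± 3.74 at LOC111882013. Nitrate reductase (LOC111902813), the first enzyme of nitrate assimilation, was at 6.27 ± 0.822 FPKM in Cd and 1.20 ± 0.173 in CdSeNP, and at 1.26 ± 0.127 in CK and 0.254 ± 0.155 in SeNP. It was called in SeNP against CK as well, and its interaction with edgeR was 0.01 (adjusted p = 0.98). Kirola (LOC111920935) fell from 5.04 ± 0.242 to 1.19 ± 0.598 FPKM and peamaclein (LOC111902782) from 7.81 ± 0.369 to 1.97 ± 1.11. The proline-rich protein DC2.15 (LOC111904704) was at 5.98 ± 4.28 FPKM in Cd and 0.704 ± 0.823 in CdSeNP, with a wide spread. In all, the authors' deposited table listed 251 genes higher and 182 lower in CdSeNP, of 23096 tested.

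The number of cadmium-changed genes that moved back toward CK with the nanoparticles was counted over the 1119 genes called in Cd. Of these, 121 (10.8%) were called the opposite way in CdSeNP against Cd, 92 that had risen and 29 that had fallen, and 1 moved further the same way. The value from independent lists was 9.8, and 5 simulations of unchanged groups sharing the Cd libraries gave 4 to 10 false calls. For the 121 genes, 107 were not called in CdSeNP against CK. Of all 1119 genes, 341 were called the same way in CdSeNP against CK, some of the 121 among them, and 671 were called neither in CdSeNP against Cd nor in CdSeNP against CK. Expansin-A15 (LOC111877762) was at 0.239 ± 0.186 FPKM in CK, 3.32 ± 1.15 in Cd, 1.16 ± 0.335 in CdSeNP and 1.69 ± 0.284 in SeNP, where it was called against CK too (SD, n = 3). HVA22-like protein a (LOC111879112) stood at 0.164 ± 0.028, 2.26 ± 0.347 and 0.941 ± 0.312 FPKM in CK, Cd and CdSeNP, and a stearoyl desaturase (LOC111876863) at 0.009 ± 0.015, 1.06 ± 0.203 and 0.362 ± 0.054 FPKM in the same order. The vicilin-like gene LOC111919377 came down to 17.0 ± 1.11 from 36.9 ± 2.46 FPKM. An added locus without a description (chromosome 8, 196684998 to 196685435) was at 0.085 ± 0.084 FPKM in CK, 4.01 ± 1.21 in Cd and 1.06 ± 0.659 in CdSeNP. In edgeR refits the count was 109 with all libraries, 64 without Cd 2 and 118 without CK 2. The call of LOC111879112 ended without CdSeNP 1. Because both comparisons use the Cd libraries, part of the excess may come from them, and the simulations do not show how much.

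Genes called in Cd and in SeNP against CK overlapped. The same direction was called at 345 genes, 242 higher and 103 lower in both, and the opposite direction at 10. Independent lists would share 16.5 in the same direction. Simulated unchanged groups with the same controls shared 7 to 9 false calls, which does not show how much the shared controls add to the real lists. Splitting the controls would leave fewer than 2 libraries in 1 of the parts, so part of the excess may come from the shared controls. The overlap was 255 in edgeR refits with all libraries and 340 without CK 2. It was 146 without CK 1, 112 without CK 3, 197 without Cd 1, 158 without Cd 2, 193 without Cd 3, 128 without SeNP 1, 108 without SeNP 2 and 116 without SeNP 3.

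CdSeNP was also compared with SeNP, which shows cadmium's effect where nanoparticles were present. Photosynthesis genes were lower at 29 and higher at 8 (adjusted p = 1.1e-15, Fisher's exact test); 7 of the 8 are cupredoxins and the other is stress enhanced protein 2. The 4 called genes of chlorophyll synthesis were lower (adjusted p = 0.013, Fisher's exact test). Glutamyl-tRNA reductase 1 (LOC111877439), the first committed enzyme of that pathway, was at 469 ± 5.56 FPKM in SeNP and 190 ± 2.81 in CdSeNP, and geranylgeranyl diphosphate reductase (LOC111909735) at 1075 ± 25.2 and 434 ± 22.9 (SD, n = 3). Of the genes called in SeNP against CK, 215 were called the opposite way here and 1 the same way. Independent lists would give 17.1 opposite, and 5 simulations of unchanged groups sharing the SeNP libraries gave 3 to 9 false calls. The 215 became 205 in edgeR refits with all libraries. It became 143 without CK 3, 121 without SeNP 1, 100 without SeNP 2 and 127 without SeNP 3. Part of the excess may come from the SeNP libraries used in both, and the simulations do not show how much. The authors' deposited table listed 741 genes higher and 143 lower, of 22862 tested.

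Between the single treatments, 30 photosynthesis genes were higher in SeNP than in Cd and 0 lower (adjusted p = 2.6e-15, Fisher's exact test), and at an absolute log2 fold change of at least 2 the call ended with 4 higher (adjusted p = 0.12). The ORG2 genes LOC111878349 and LOC111878326 had no counts in SeNP. Ferritin LOC111919692 was at 83.1 ± 3.90 FPKM in SeNP and 5.85 ± 0.549 in Cd, and Nramp3 (LOC111896352) at 22.5 ± 0.492 and 69.5 ± 2.57 (SD, n = 3). In all, 154 genes were higher and 347 lower in SeNP in the authors' deposited table, of 22978 tested. Scaling to library totals moved every log2 value by -0.101 and left 121 higher and 347 lower. With only called genes listed, this shift could remove higher calls alone.

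**Figure D3:**
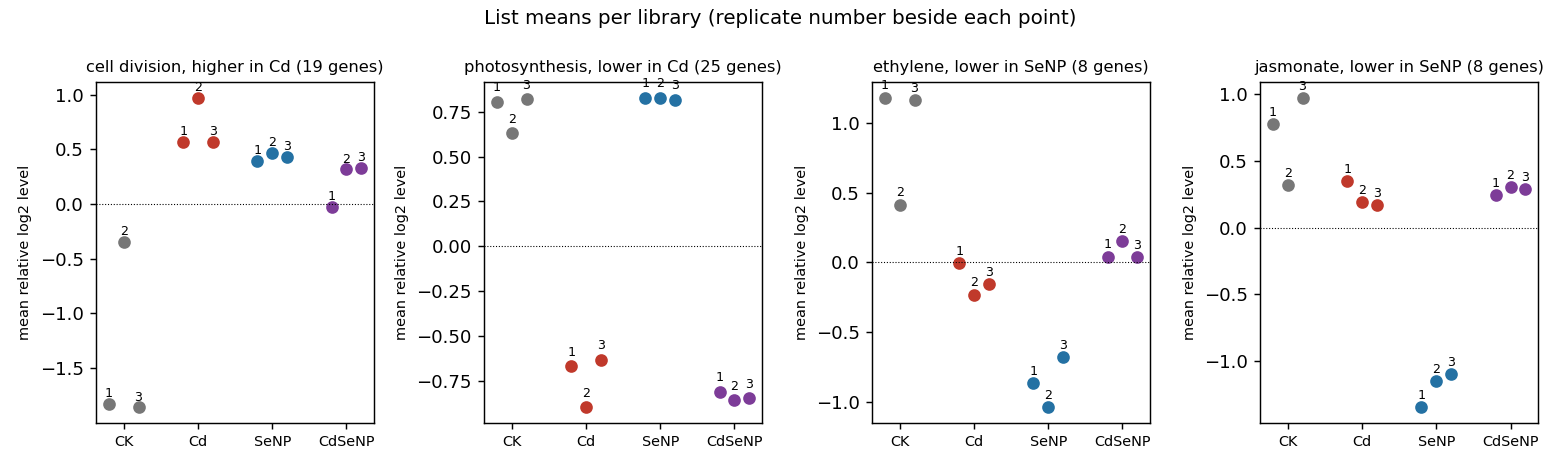
Mean log2 level per library of called list members with values in all 12 libraries, relative to their mean over the libraries (vertical axis). Shown are 19 cell division genes called higher and 25 photosynthesis genes called lower in Cd than CK, and 8 ethylene and 8 jasmonate genes called lower in SeNP than CK. The differences between those groups were therefore fixed by the choice of genes. For cell division CK 2 stood at -0.345 against -1.82 in CK 1 and -1.86 in CK 3, while for photosynthesis the controls lay between 0.63 and 0.82.

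Whether the Cd response differed with nanoparticles was tested as an interaction over 575 genes with values in all 12 libraries, with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment. At an adjusted p under 0.05, 424 differed, 260 with a more positive and 164 with a more negative Cd response when nanoparticles were present. These 575 genes were called in several tables, so the count is no rate for all genes. The interaction also rests on the controls, of which CK 2 stood apart. Without CK 2 443 genes differed. Leaving out a control that often lay nearer the treated level can widen differences, so that count is no independent support. Copper transporter 5 (LOC111893192) stood at 149 ± 10.3 FPKM in CK, 125 ± 8.53 in Cd, 47.1 ± 7.68 in SeNP and 131 ± 3.8 in CdSeNP, and zinc transporter 1 (LOC111880346) at 18.3 ± 0.936, 10.1 ± 1.03, 1.84 ± 0.369 and 11.4 ± 1.88 in that order (SD, n = 3). Neither was called in Cd against CK, and both were higher in CdSeNP than in SeNP. Their interaction with edgeR was 1.81 (adjusted p = 1.5e-05) and 3.58 (adjusted p = 1.2e-06) on the log2 scale. With edgeR it was 2.84 for the iron superoxide dismutase (adjusted p = 1.2e-07) and 3.38 for dehydrin Rab18 (adjusted p = 3.6e-05). With edgeR no difference was called for oligopeptide transporter 3 (0.26, adjusted p = 0.18), Nramp3 LOC111896352 (-0.05, adjusted p = 0.76) or LHCII type 1 (-0.13, adjusted p = 0.47).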

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

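Every test in this part was chosen after its result was seen, except the counts with a library left out, the test of the interaction and the count of its splits.

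The Cd response differed with nanoparticles at 424 of 575 genes in edgeR's interaction test, and 43 of the 72 named genes with values in all libraries were among them. The values below are differences of log2 fold changes, positive where the Cd response was more positive with nanoparticles. Among genes of metal and redox balance, the interaction was 3.58 for zinc transporter 1, 1.81 for copper transporter 5, 1.81 for vacuolar iron transporter homolog 4 (LOC111899502), 2.84 for the iron superoxide dismutase and -1.69 for a copper-zinc superoxide dismutase (LOC111882980). It was 0.77 for ubiquinol oxidase 2, -0.72 and -0.98 for the ferritins LOC111879873 and LOC111919692, 2.72 and 2.40 for the cupredoxins LOC111881903 and LOC111881904, and -2.92 for basic blue protein.

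Among stress and hormone genes, the interaction was 3.38 for dehydrin Rab18, 3.44 for syntaxin-121, 3.19 for WRKY 31, 2.74 for CML38, 2.87 for TIFY 10A, 1.82 for CYP707A2, 1.41 for PP2-B15, 1.35 for 1-aminocyclopropane-1-carboxylate synthase 3 and 1.28 for jasmonate-induced oxygenase 2. Among cell wall and cuticle genes it was 2.60, 2.65 and 2.24 for the xyloglucan enzymes LOC111909622, LOC111909624 and LOC111909625, 2.53 for leucine-rich repeat extensin-like protein 5, -4.24 for expansin-A15 and 0.64 for ECERIFERUM 26. It was -3.06 and -3.61 for the GDSL esterase/lipases LOC111886836 and LOC111886847, -3.56 for lipid-transfer protein 1, -1.65 for the lipid-transfer protein LOC111915888 and -3.29 for glycine-rich protein 5-like.

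For photosystem genes the differences were small, -0.33 for chlorophyll a-b binding protein 5, -0.25 for chlorophyll a-b binding protein 13 and -0.20 for photosystem I subunit III. Genes of DNA replication gave -2.76 for proliferating cell nuclear antigen (LOC111919730) and -1.84 for histone H4. The interaction rests on the controls. The 19 cell division genes called higher in Cd than CK and with values in all libraries were chosen for that difference. Over them CK 1 and CK 3 had mean relative log2 levels of -1.82 and -1.86. CK 2 was at -0.345 and the treated libraries were between -0.025 and 0.97. Low levels in CK 1 and CK 3 may therefore account for part of such negative values. The remaining values were -3.05 for HVA22-like protein a, 1.72 for dirigent protein 22, 0.76 for the isoflavone reductase homolog, -1.74 for the vicilin-like gene LOC111919377, 0.51 for the vicilin LOC111921670, -2.69 for kirola and -0.64 for a locus on chromosome 5 described as hypothetical protein LSAT_5X97381.

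Many of the SeNP calls, but not all, followed a difference among the controls. Over all 750 genes CK 2 had a median place of 0.492 between the other controls and SeNP (quartiles 0.24 and 0.673). It lay over 0.3 at 516 of them (68.8%). The median was 0.668 over the 282 genes higher in SeNP and 0.345 over the 468 lower. A plant state that also varies among untreated plants may account for the cell division genes (0.703, with the lower quartile at 0.649, above the bound of 0.3), and over all SeNP calls it stays open, as the quartiles lie on both sides of the bound. For the 12 antioxidant and metal transport genes as a set, the place of CK 2 was 0.158, with the upper quartile at 0.27. These values argue against a state carried by CK 2, and a state that CK 2 does not carry was not tested. The state carried by CK 2 stays open for 3 of the 12 genes. These are the copper-zinc superoxide dismutase LOC111897744 (0.514) and the cation exchangers LOC111893170 (0.428) and LOC111919987 (0.591). RNA of SeNP plants mixed into CK 2 would give all genes a like place on the linear scale, where mixed RNA adds, yet the 12 genes had 0.204 (quartiles 0.11 and 0.285) against 0.497 for all calls (quartiles 0.298 and 0.628), which argues against mixing as the cause of the whole pattern. The linear scale was taken up after the log2 scale, where the quartiles overlapped, a smaller mixed share beside another cause was not tested, and an effect of the nanoparticles on the same genes stays open.

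Cell division genes were higher in Cd and in CK 2. The lean of CK 2 toward Cd was not limited to them, as its place was over 0.3 at 728 of all 1119 Cd calls (65.1%). For CdSeNP against CK it was over 0.3 at 193 of 588 calls (32.8%). The count of 116 genes higher in Cd was 90 with edgeR and all libraries. It became 36 without CK 1, 23 without CK 3, 37 without Cd 1, 18 without Cd 2 and 40 without Cd 3. A plant state that also varies among untreated plants, such as the share of young dividing tissue, may account for these genes, with a median place of CK 2 of 0.68 (quartiles 0.618 and 0.715). An effect of cadmium on the same genes stays open, because plant age and tissue share were not measured here.

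For photosynthesis genes lower in Cd, 24 of 30 genes stayed past the fold threshold with library totals. Library totals moved every log2 value by 0.119, where the median over the list's called genes was -1.246. The choice between them and the authors' scaling therefore mattered little. Library totals are only 1 other scaling, so a cause in the scaling stays open. The tables argue against a plant state shared with CK 2, whose place was 0.108 (quartiles 0.039 and 0.135). An effect of cadmium stays open as a hypothesis, and other technical explanations were not tested.

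Each comparison of 3 libraries with 3 allows 10 splits, too few for a share under 0.05. The real split was the 1 with the most calls in each comparison, but the listed genes had been chosen for it. Refits of the listed genes called 972 genes for Cd against CK in the real split and at most 2 in another. For SeNP against CK these numbers were 653 and 2, for CdSeNP against CK 491 and 3, for CdSeNP against Cd 422 and 2, for CdSeNP against SeNP 882 and 0, and for SeNP against Cd 494 and 0. For the interaction the real value was 424 and the highest of the others 97, over 100 splits, which decides nothing because the 575 genes had been chosen for differing between the real groups.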

How the results depend on the processing

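Scaling to library totals and the focus on CK 2 were chosen after the results were seen; the other tests below were planned. No named gene changed direction in a refit, and a minimum mean of 1 FPKM in the higher group moved no count of calls by over 1.5 times. Over single libraries left out, 516 calls of named genes were kept and 30 were lost, and library totals ended 4, edgeR 1, DESeq2 0 and the block 0 of 91. Calls of the further genes chosen after their values were seen are not in these counts. List calls were kept in 139 cases of a library left out, lost in 23 and turned or emptied in 6. These cases take all 12 libraries for each list call. Many of the 139 leave out a library that the comparison does not use, where the list's genes cannot change, so they show no stability. Of 14 list calls, library totals ended 4, DESeq2 3, NR descriptions alone 3, Swiss-Prot alone 4, an adjusted p limit of 0.01 3, and edgeR 5, leaving 9. Refits with fewer libraries at a fixed p limit can lose calls from the smaller number alone, and otherwise the cause was not tested. Values of genes outside the tables set the limit here, since a gene entering under another setting cannot be seen. TMM and DESeq2 size factors estimated on all genes, no filter on low counts, other pseudocounts, 1 fit over all 12 libraries for the pairwise comparisons, set tests with an estimated correlation, split controls, and the return and the overlap with no fold threshold were not run.

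At an absolute log2 fold change of at least 2, 160 genes were higher and 24 lower in Cd than CK, 14 and 39 in SeNP than CK, 60 and 37 in CdSeNP than CK, 13 and 20 in CdSeNP than Cd, 129 and 19 in CdSeNP than SeNP, and 23 and 81 in SeNP than Cd. There the return held 11 genes, the overlap of Cd with SeNP 12, and 1 list passed. With no fold threshold at least 5181 genes changed in Cd against CK, 3638 in SeNP against CK, 3356 in CdSeNP against CK, 5919 in CdSeNP against Cd, 6030 in CdSeNP against SeNP and 4844 in SeNP against Cd. At an adjusted p under 0.01, 167 genes were higher in SeNP than CK and the overlap was 224. An edgeR refit with library totals, which changes the test and the scaling together, gave 176 genes higher in SeNP than CK and 211 lower in Cd than CK.

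EdgeR refits with all libraries gave 669 genes higher and 303 lower in Cd than CK, 205 and 448 in SeNP than CK, and 206 and 285 in CdSeNP than CK. Leaving out 1 library in turn gave 345 to 777 genes higher and 205 to 311 lower in Cd than CK, 63 to 281 and 213 to 463 in SeNP than CK, and 133 to 233 and 219 to 288 in CdSeNP than CK. The highest counts of these 3 comparisons came without CK 2. CdSeNP against Cd gave 197 to 241 and 122 to 164, CdSeNP against SeNP 678 to 718 and 126 to 138, and SeNP against Cd 133 to 146 and 287 to 312. The interaction ranged from 403 to 443, the return from 64 to 118, the overlap from 108 to 340 and the lists past the threshold from 8 to 14. The 8 came without CK 1 and without CK 3. Genes of abscisic acid lower in Cd ranged from 1 without CK 1, where the list's lean turned, to 7. Cell division genes higher in CdSeNP than CK ranged from 0, without CK 1, CK 3 or any CdSeNP library, to 20 without CK 2.

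Whether the replicate numbers pair the libraries stays open. Of 18 same-numbered pairs 9 had a correlation of deviations over 0.1. The values ran from -0.226 for CK 3 with CdSeNP 3 to 0.386 for CK 2 with Cd 2. In 19 of 36 cases a library correlated best with its own number among the 3 libraries of another group. With the number as a block, 309 genes were lower in Cd than CK, against 303 with edgeR without a block. The number higher with the block differed by fewer than 5 from the authors' 799. EdgeR without a block gave only 669 higher, so the block added many higher calls in this comparison. The block gave 280 genes higher and 438 lower in SeNP than CK, 229 and 281 in CdSeNP than CK, 240 and 158 in CdSeNP than Cd, 741 and 143 in CdSeNP than SeNP, and 151 and 336 in SeNP than Cd. Without a block edgeR gave 205 and 448, 206 and 285, 249 and 173, 740 and 142, and 153 and 341 in that order. The block left 425 genes whose Cd response differs with SeNP, 106 genes in the return, 334 in the overlap and 11 lists. Without a block these were 424, 109, 255 and 9.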

Other observations

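The genes in the first paragraph were chosen after their values were seen. A group of added loci without RefSeq IDs on chromosome 5, described as hypothetical proteins, had low levels in CK and SeNP and high levels in Cd and CdSeNP. The locus at 238238514 to 238239246 (LSAT_5X97421) had 0.219 ± 0.127 FPKM in CK, 115 ± 1.87 in Cd, 0.242 ± 0.087 in SeNP and 121 ± 11.6 in CdSeNP (SD, n = 3). Its neighbour at 238251525 to 238252082 (LSAT_5X97381) had 0.841 ± 0.104, 73.3 ± 3.09, 1.25 ± 0.06 and 66.1 ± 5.19 FPKM in the same order. Further along, 6 loci between 238550163 and 238707909 share the description LSAT_5X98220. One of them, at 238628264 to 238628856, had no counts in CK, 9.31 ± 0.765 FPKM in Cd and 9.96 ± 0.789 in CdSeNP. In the authors' deposited table all 8 loci were higher in Cd than in CK. Whether loci with the same description are near-identical copies was not tested, and how reads were divided between them is not given in the sources used here.

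Lists of hormone and defence genes were higher in CdSeNP than in SeNP, in a table where most calls were higher. On the ethylene list 23 genes were higher and 1 lower (adjusted p = 0.63, Fisher's exact test), on the jasmonate list 12 and 0 (adjusted p = 0.72, Fisher's exact test), and among WRKY factors 14 and 0 (adjusted p = 0.6, Fisher's exact test). On the abscisic acid list 19 were higher and 0 lower (adjusted p = 0.4, Fisher's exact test), and on the pathogen defence list 36 and 4 (adjusted p = 0.85, Fisher's exact test). None of these 5 lists passed the test against the rest of the table.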
